A study of Mus musculus with 8 samples.

How the data were processed

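Total RNA of mouse liver was measured on 8 Affymetrix MG-U74Av2 arrays, 2 arrays in each of 4 groups made by AP20187 treatment and Atf4 genotype. The deposited table, made by the authors, holds linear ratios in steps of 0.01, for most probe sets to their own median over the 8 arrays. This was tested on the table: 10714 of 12488 probe sets (85.8%) had a median of at least 0.99 and the other 1774 (14.2%) a median below that, as if a floor had been set under the divisor of dim probe sets. How signals were summarised, scaled between arrays and divided is not given in the sources used here. Groups were taken from the source names and descriptions. For untreated Atf4-/- replicate 1 these give different genotypes, and the source name was used. The labels do not say whether the arrays of a group came from separate mice or litters, and if they did not, the p-values measure only the spread between these samples. Signal over background is unknown in a table of ratios, and no detection calls were used here.

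After 66 control probe sets were left out, 12422 were tested. Of these 10833 had 1 gene, 396 several and 1193 none; 10817 were matched to the gene table by gene identifier, and 8251 genes were covered, 2073 by more than 1 probe set. The means of the 8 columns after trimming 2% lay between 0.937 and 0.980, at most 3.23% from their median, inside the planned 10%, so that the table was kept as deposited. Values were log2(ratio + 0.1). In limma 3.58.1 (R 4.3.3, statmod 1.5.0) 4 group means were fitted to all 8 arrays, contrasts were moderated by eBayes without trend or robust fitting (4 residual and 2.37 prior degrees of freedom, prior SD 0.308), and p-values were adjusted by Benjamini and Hochberg over the 12422 probe sets in each of 5 comparisons, with a threshold of 0.05. The median SE of a contrast of 2 against 2 arrays was 0.32. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

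All 37 gene lists, with 511 measured genes of which 5 stand in more than 1 list, were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, with adjustment over the 37 lists of a comparison. Camera called 12, 7, 8, 2 and 8 lists in the AP20187 effect in Atf4+/+, that in Atf4-/-, their difference, and the genotype comparisons without and with AP20187, and with an estimated correlation 0 in each. The gene-wise counts inside a list were adjusted over the list alone, which does not allow for the search over 37 lists and 5 comparisons. Aliases of 3 list genes that had pointed to other genes were repaired after list results had been seen. The lists were written from general knowledge and not from these samples.

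The design, the lists and a first set of alternatives were fixed before the data were examined. Further alternatives were chosen after seeing the data, and 4 points of the design had to be changed once the unit was known. The planned pseudocount of 16 was for signal values and became 0.1. The planned filter at the 25th percentile of the mean was left out, since the mean of ratios to the median does not measure brightness. The probe set of a gene was chosen by a row median of at least 0.99, then a plain probe set name, then the smallest SD within groups, in place of the highest mean. Neither planned rule for the scale fitted a ratio. Genes were named by a rule: Atf4 and Eif2ak3 in each comparison; the 10 largest rises and falls past the test, or, with fewer than 5 past it in a direction, the 5 with the smallest p in that direction, given as not past the test; up to 4 genes with the smallest p in each list described; and 16 known ATF4 targets wherever measured. Clone names, predicted genes and sex-linked genes were left out. Chac1, Fgf21 and Sesn2 were not analysed here, for want of a probe set naming them alone. Genes placed beside others outside this rule are named as chosen after their values were seen.

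The fit was tested on simulated data of the same size, with the spread of each probe set drawn from the fitted prior. With 200 of 12422 probe sets changed, averaged over 10 simulations, 0% of those changed by 1 on the log2 scale were called in each of the 5 comparisons. Of those changed by 2, 38.4%, 40.2%, 0%, 39.9% and 41.9% were called in the order above, and of those changed by 3, 76.1%, 78.5%, 50.6%, 79.1% and 79.4%. Of 740 camera tests of unchanged simulated lists with the preset correlation 3.92% had a p under 0.05, and a list shifted by 0.5 was called in 20 of 20 runs. The simulated genes varied independently of each other, so that these rates do not cover lists whose genes vary together. The alternatives were other normalizations, pseudocounts, filters, probe set choices, moderation, array weights, thresholds, groupings of the doubted arrays and leaving out each array. Correlations across arrays carry exact permutation p-values, two-sided.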

Results

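Gene expression was measured on 8 oligonucleotide arrays of mouse liver, 2 arrays in each of 4 groups. All mice carried a liver transgene for Fv2E-PERK, a fusion of the kinase PERK with a dimerization domain. The drug AP20187 joins this domain and so switches on the integrated stress response. The siblings were either Atf4+/+ or Atf4-/-, and Atf4 encodes the transcription factor whose translation that response raises. Livers were untreated or treated with AP20187, which the series title sets against mock injection. The deposited value of a probe set was a linear ratio, to its own median over the 8 arrays in 85.8% of the table. In the other 14.2% the median lay below 0.99, as if a floor had been set under the divisor. The brightness of a probe set is therefore unknown, and the number of arrays limits the precision. Of 12422 probe sets tested, 10833 named 1 gene. Pearson's r of the log2 ratios across probe sets was 0.268 between the untreated Atf4+/+ arrays, 0.260 between the untreated Atf4-/- arrays, 0.312 between the treated Atf4+/+ arrays and 0.365 between the treated Atf4-/- arrays. Arrays of different groups correlated as highly in part, with 0.40 between replicate 1 of untreated and of treated Atf4+/+ and 0.293 between untreated Atf4+/+ replicate 1 and untreated Atf4-/- replicate 2. Treated Atf4+/+ replicate 2 had the lowest values, 0.0974 to 0.121 with the untreated arrays. Probe sets are not independent replicates.

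The targeted gene was read first, as a check of the genotype labels. The 1 probe set for Atf4 (GRCm38.p6 chromosome 15, 80255184 to 80257545) had ratios of 4.17 and 5.75 in the treated Atf4+/+ livers and 0.25 and 0.33 in the treated Atf4-/- livers. In untreated livers the ratios were 2.36 and 0.30 in the arrays labelled Atf4+/+ and 0.29 and 1.67 in the arrays labelled Atf4-/-. Untreated Atf4+/+ replicate 2 and untreated Atf4-/- replicate 2 therefore stood on the side opposite to their labels. In untreated Atf4-/- replicate 1 the source name gave Atf4-/- and the description gave Atf4+/+, and its ratio of 0.29 was low. Which part of the gene was deleted is not given in the sources used here, and whether this probe set lies in it is unknown. The log2 difference between Atf4-/- and Atf4+/+ was -3.69 ± 0.99 with AP20187 (SE, 2 against 2 arrays, limma adjusted p = 0.712) and -0.26 ± 0.99 without (limma adjusted p = 0.999). This SE pools the spread within all 4 groups. The 2 untreated arrays differed by 2.62 (labelled Atf4+/+) and 2.18 (labelled Atf4-/-) on the log2 scale, and the treated pairs lay closer together. The SE and p with AP20187 therefore do not read the spread of the treated arrays alone. The untreated value took the opposite sign without the array labelled untreated Atf4+/+ replicate 1 (1.05) and without the array labelled untreated Atf4-/- replicate 1 (0.84). Eif2ak3, the gene of PERK, differed by -0.21 ± 0.40 with AP20187 and -0.02 ± 0.40 without (SE, limma adjusted p = 0.974 and 0.999). The AP20187 effects, their difference and the comparison of untreated genotypes all use these untreated arrays, and in them Atf4+/+ and Atf4-/- are the genotypes as labelled.

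**Figure D1:**
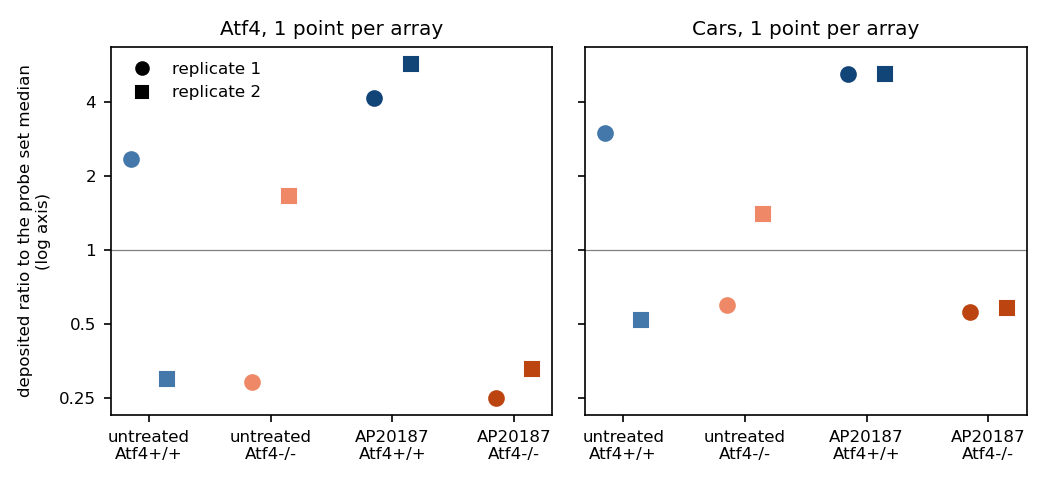
Deposited ratio to the probe set median (log axis) of Atf4 and of Cars in each of the 8 arrays, 1 point per array, by labelled group. For Atf4 both treated Atf4+/+ arrays lay at 4.17 or above and both treated Atf4-/- arrays at 0.33 or below, while each untreated group held 1 high and 1 low array. Cars, chosen for this plot after its values were seen, split the untreated arrays in the same way.

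The first comparison asked what activation of the kinase changed in Atf4+/+ livers, measured against the arrays labelled untreated Atf4+/+. B3galt1, which encodes a galactosyltransferase of glycan synthesis, rose with AP20187 (log2 change 3.39 ± 0.21, SE, limma adjusted p = 0.0279). Its ratio was 0.29 ± 0.0424 untreated and 4.0 ± 0.46 treated (SD, n = 2 each). Among the genes named for this comparison the largest values belonged to the stress genes Nupr1, Trib3 and Atf3. Nupr1, a stress-induced chromatin protein gene, had a log2 change of 6.74 ± 0.86 (SE, 2 against 2 arrays), with ratios of 0.15 in both untreated arrays and 28.5 ± 14.0 in the treated ones (SD, n = 2). The pseudokinase gene Trib3 stood at 5.34 ± 0.67, the transcription factor gene Atf3 at 5.18 ± 0.46 (its other probe sets at 4.75 and -0.27) and Ddit3, which encodes CHOP, at 4.18 ± 0.48. Genes of serine and one-carbon synthesis stood beside them, with Psat1 at 4.57 ± 0.50 and Mthfd2 at 2.92 ± 0.30 (its other probe set at 0.87). Among the smallest p-values were also Ifrd1 (2.96 ± 0.28) and the histone gene H1f2 (2.25 ± 0.23), both with higher values. Lower values with the smallest p belonged to the adaptor gene Crk (-2.70 ± 0.23), Mrvi1 (-2.13 ± 0.21), the spindle motor gene Kif11 (-2.23 ± 0.23), the basement membrane gene Nid2 (-2.70 ± 0.35) and the connexin gene Gja3 (-1.75 ± 0.25). Atf4 itself had a value of 2.33 ± 0.99 and Eif2ak3 0.25 ± 0.40.

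B3galt1 was the 1 probe set of 12422 past the limma test over all probe sets. There were 1130 with an unadjusted p under 0.05 (594 higher, 536 lower), where 621.1 would have it by chance. Without any 1 of the 8 arrays the log2 change of B3galt1 was 3.28 to 3.51 and its limma adjusted p 0.155 to 0.322, so that the count of probe sets past the test was then 0.

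Of 14 stress regulators of the integrated stress response measured, 12 had values above 0 in Atf4+/+ livers, 8 rose adjusted over the list alone and 6 did not pass. Camera called the list higher (median log2 change 1.25, camera adjusted p = 6.01e-10, adjusted p = 0.0785 with an estimated correlation). Among the genes that rose were Nupr1, Trib3, Atf3, Ddit3, the growth inhibitor gene Ddit4 (2.61 ± 0.61, SE), Atf5 (1.89 ± 0.48) and the phosphatase subunit gene Ppp1r15a (0.96 ± 0.26), while Cebpb did not pass (0.83 ± 0.39). The mean of the list was -0.78 and -0.68 in the untreated and 1.24 and 1.59 in the treated Atf4+/+ arrays. Of 20 transfer RNA synthetases, which charge transfer RNA with amino acids, 18 had values above 0 and 9 rose adjusted over the list alone, among them Gars (1.14 ± 0.22), Aars (1.13 ± 0.25), Nars (1.05 ± 0.24) and Lars (1.16 ± 0.27). Their median was 0.77 (camera adjusted p = 5.56e-10, adjusted p = 0.211 with an estimated correlation). In amino acid and one-carbon synthesis 3 of 10 genes rose adjusted over the list alone, namely Psat1, Mthfd2 and Psph (1.10 ± 0.20). Asns (0.97 ± 0.33, its other probe set at 1.83) and Phgdh (-0.02 ± 0.32) did not pass. The median of that list was -0.01, its mean 0.78 and its camera direction up (camera adjusted p = 0.0282, adjusted p = 0.421 with an estimated correlation). By fry, which tests whether a set moves on balance 1 way, these 3 lists had adjusted p = 0.00566, 0.0282 and 0.0398. Slc1a4 (1.11 ± 0.23) was the 1 of 12 amino acid transporters that rose adjusted over the list alone, with Slc3a2 at 0.73 ± 0.22 and Slc7a11 at -0.31 ± 0.82, and camera did not call that list. The call of Slc1a4 ended without any 1 of the 4 Atf4+/+ arrays and without either treated Atf4-/- array.

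Single arrays carried some of these counts. The count of stress regulators fell to 4 without untreated Atf4+/+ replicate 2. The count of synthetases fell to 0 without untreated Atf4+/+ replicate 2 or treated Atf4+/+ replicate 2, to 3 without treated replicate 1 and to 5 without untreated replicate 1. Without both untreated arrays whose Atf4 level stood against their labels, an alternative chosen after seeing the data, the counts were 6 stress regulators, 0 synthetases and 2 amino acid synthesis genes. Camera did not call amino acid synthesis without treated Atf4+/+ replicate 1 (median 0.30, adjusted p = 0.0867) or replicate 2 (-0.13, adjusted p = 0.122). The median of that list was 0.05 and 0.15 without untreated Atf4+/+ replicates 1 and 2.

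Of 11 growth arrest genes 4 rose with AP20187 in Atf4+/+ livers adjusted over the list alone: the cell cycle inhibitor gene Cdkn1a (2.78 ± 0.35, SE), Gadd45a (3.26 ± 0.60), Gadd45g (2.07 ± 0.44) and Btg2 (1.32 ± 0.32). Camera called the list higher (median 0.15, camera adjusted p = 0.00277, adjusted p = 0.421 with an estimated correlation). Of 14 immediate early genes Klf6 (1.19 ± 0.24) and Myc (3.96 ± 0.98) rose adjusted over the list alone, and Jun (0.80 ± 0.29) and Egr1 (0.92 ± 0.39) did not pass. Their median was 0.39 (camera adjusted p = 0.0235, adjusted p = 0.421 with an estimated correlation). Of 17 translation factors 0 passed adjusted over the list alone by limma, and 4 had an unadjusted p under 0.05: Eif3c (0.79 ± 0.22), Eif3a (1.06 ± 0.31), Eif1a (0.98 ± 0.30) and Eif5 (1.07 ± 0.35). Their median was 0.48 (camera adjusted p = 0.000121, adjusted p = 0.421 with an estimated correlation). Acute phase genes, which the liver expresses in inflammation, gave 19 of 23 values above 0 and a median of 0.41 (camera adjusted p = 9.97e-05, adjusted p = 0.421 with an estimated correlation). Of these 0 passed adjusted over the list alone by limma, and 4 had an unadjusted p under 0.05: Apcs (1.83 ± 0.38), Lcn2 (3.05 ± 0.71), Saa2 (2.09 ± 0.72) and Hamp (0.93 ± 0.38). All 7 genes of MHC class II, which present antigen, had values above 0 against the arrays labelled untreated Atf4+/+ (median 0.61, camera adjusted p = 0.0131, adjusted p = 0.421 with an estimated correlation). By limma 0 of them passed adjusted over the list alone, and 1, H2-DMb1 (1.51 ± 0.41), had an unadjusted p under 0.05.

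Leaving out single Atf4+/+ arrays moved some of these lists. Camera with its preset correlation still called the arrest list when any 1 such array was left out. The median of the arrest list was 0.36 without treated replicate 1, 0.30 without treated replicate 2, 0.30 without untreated replicate 1 and 0.23 without untreated replicate 2. The count of arrest genes fell to 2 without either replicate 2. Camera did not call immediate early genes without treated replicate 2 (0.31, adjusted p = 0.136) or untreated replicate 2 (0.21, adjusted p = 0.106), and their median was 0.69 without untreated replicate 1. The count of immediate early genes fell to 0 without each of these 3 arrays and was 4 without treated replicate 1. Camera did not call MHC class II genes without treated replicate 1 (0.59, adjusted p = 0.0849), and their median was 0.33 without untreated replicate 1.

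Of the lists of liver metabolism 4 were called lower with AP20187 by camera in Atf4+/+ livers: cholesterol synthesis, bile acids, the respiratory chain and the urea cycle with amino acid breakdown. The last is also called the urea cycle list for short, though it holds enzymes of amino acid breakdown as well. None of these calls held with an estimated correlation (adjusted p = 0.421, 0.421, 0.682 and 0.549 with an estimated correlation). Fatty acid synthesis (median -0.61), glucose metabolism (-0.39), cytochromes P450 (-0.22) and fatty acid oxidation (-0.20) were not called. All 15 genes of cholesterol synthesis had values below 0 and 3 fell adjusted over the list alone: Mvd (-1.92 ± 0.44, SE), Dhcr7 (-1.70 ± 0.42) and Msmo1 (-1.74 ± 0.46). Idi1 stood at -1.92 ± 0.61 and the median at -1.14 (camera adjusted p = 1.22e-06, adjusted p = 0.421 with an estimated correlation). The list's mean was 0.30 and 1.28 in the untreated and -0.03 and -0.68 in the treated arrays. Untreated replicate 2, the highest of these, also had a ratio of 5.37 for the clock gene Dbp, while treated replicate 2, the lowest of these, had the next highest ratio of Dbp at 3.87. The clock genes Nr1d1, Arntl and Cry1 stood at 5.21, 0.2 and 0.25 in untreated replicate 2. In treated replicate 2 they stood at 1.51, 1.13 and 1.27. Of 15 clock genes measured, these and Dbp were chosen outside the naming rule, after values had been seen. In bile acid synthesis and transport 1 of 9 genes, the sterol hydroxylase gene Cyp8b1 (-1.86 ± 0.38), fell adjusted over the list alone, and Nr0b2 (-1.62 ± 0.55) and Slc10a1 (-0.86 ± 0.32) did not pass. The median of the list was -0.53 (camera adjusted p = 0.0282, adjusted p = 0.421 with an estimated correlation). The respiratory chain (19 genes, with Sdhd at -0.79 ± 0.34) had a median of -0.34 (camera adjusted p = 0.0131, adjusted p = 0.682 with an estimated correlation). The urea cycle and amino acid breakdown (18 genes, with Gldc at -0.94 ± 0.43 and Hgd at -0.66 ± 0.28) had a median of -0.37 (camera adjusted p = 0.0282, adjusted p = 0.549 with an estimated correlation). In both of the last lists 0 genes passed adjusted over the list alone by limma and 0 had an unadjusted p under 0.05.

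Leaving out 1 Atf4+/+ array ended calls of the bile acid, respiratory chain and urea cycle lists. Without treated replicate 2 the medians were -0.88 for cholesterol, -0.32 for bile acids (camera adjusted p = 0.431), -0.16 for the respiratory chain (camera adjusted p = 0.431) and -0.11 for the urea cycle (camera adjusted p = 0.480). That array also had the lowest log2 ratio of the 5' to the 3' probe set of Actb, a measure of RNA integrity, at -0.64 against -0.19 for the next array. Both probe sets hold deposited ratios, so that this value compares the arrays with each other and gives no absolute integrity. The same ratio of Gapdh, at -0.0614 against -0.0502 for the next array, did not set it apart. The cholesterol median was -0.65 without untreated replicate 2, -1.76 without untreated replicate 1 and -1.73 without treated replicate 1. The count of 3 cholesterol genes fell to 0 without untreated replicate 2, treated replicate 2 or any 1 Atf4-/- array, and was 13 without untreated replicate 1. Without untreated replicate 1 camera did not call bile acids (-0.59, adjusted p = 0.187), the respiratory chain (-0.22, adjusted p = 0.234) or the urea cycle (-0.22, adjusted p = 0.0978). Without untreated replicate 2 it did not call the urea cycle (-0.40, adjusted p = 0.068). The bile acid count fell to 0 without either replicate 2 and was 2 without untreated Atf4+/+ replicate 1 or either treated Atf4-/- array.

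**Figure D2:**
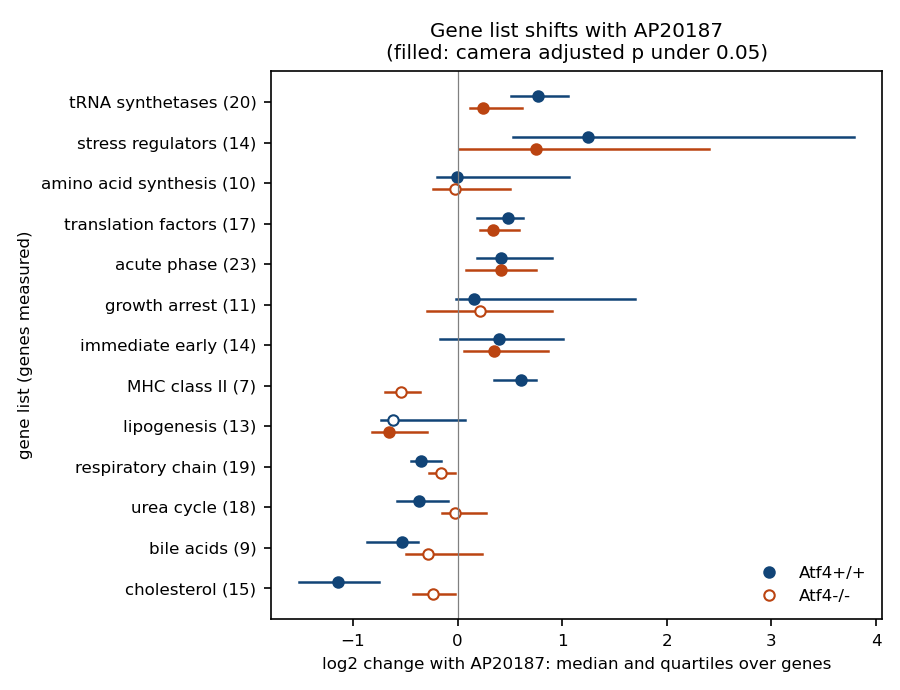
Median log2 change with AP20187 (points) and quartiles over genes (bars) of 13 gene lists in Atf4+/+ and Atf4-/- livers, 2 against 2 arrays each. The number of genes measured stands in brackets, and filled points passed camera at an adjusted p under 0.05 with its preset correlation. Stress regulators stood at 1.25 in Atf4+/+ and 0.75 in Atf4-/-, and cholesterol synthesis at -1.14 in Atf4+/+. The list marked urea cycle also holds genes of amino acid breakdown.

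**Figure D3:**
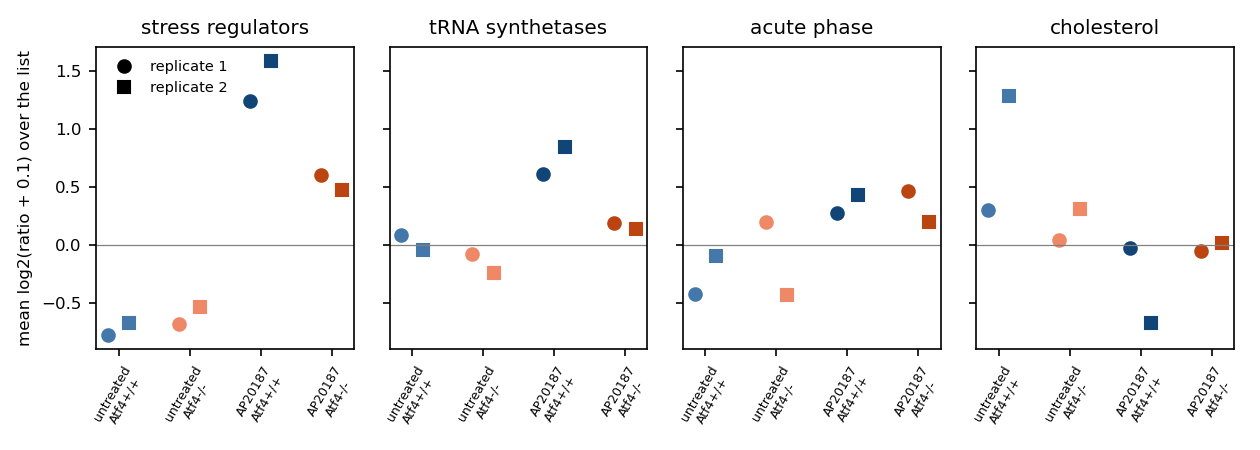
Mean of log2(ratio + 0.1) over the genes of 4 lists in each of the 8 arrays, 1 point per array. The stress regulators of the treated arrays lay at 0.47 or above and those of the untreated arrays at -0.54 or below, and the cholesterol list was highest in untreated Atf4+/+ replicate 2 at 1.28.

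The second comparison asked what the kinase changed in Atf4-/- livers, measured against the arrays labelled untreated Atf4-/-. Of 14 stress regulators 5 rose there adjusted over the list alone: Atf3 (3.13 ± 0.46, SE, 2 against 2 arrays, its other probe sets at 2.62 and -0.27), Trib3 (3.09 ± 0.67), Ddit3 (2.91 ± 0.48), Atf5 (2.54 ± 0.48) and Ddit4 (2.0 ± 0.61). The other 9 did not pass, and camera called the list with its preset correlation but not with an estimated one (adjusted p = 0.373 with an estimated correlation). The list's mean was -0.69 and -0.54 in the untreated and 0.60 and 0.47 in the treated arrays. Nupr1 stood at 0.31 ± 0.86, Psat1 at 1.23 ± 0.50, Mthfd2 at 0.54 ± 0.30 and Asns at 0.06 ± 0.33 (its other probe set at -1.81), none past the test. The smallest p-values with higher values belonged to B3galt1 (2.78 ± 0.21), Ifrd1 (2.70 ± 0.28), Mrvi1 (1.91 ± 0.21), the growth factor binding protein gene Igfbp1 (2.12 ± 0.25, its other probe set at 0.04) and the ribonucleotide reductase gene Rrm2 (1.82 ± 0.22). Those with lower values belonged to the matrix gene Dpt (-2.46 ± 0.24), Gcap8 (-1.65 ± 0.23), the chemokine receptor genes Ccr1 (-2.38 ± 0.24) and Ccr3 (-2.36 ± 0.36), and the cytokine receptor gene Il5ra (-2.11 ± 0.35). Atf4 had a value of -1.10 ± 0.99 and Eif2ak3 0.06 ± 0.40. No probe set of 12422 passed limma over all probe sets (smallest adjusted p = 0.0957, for B3galt1). There were 922 with an unadjusted p under 0.05 (530 higher, 392 lower), where 621.1 would have it by chance.

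Among the lists in Atf4-/- livers, stress regulators had a median of 0.75 (camera adjusted p = 0.000581, adjusted p = 0.373 with an estimated correlation). Of 20 transfer RNA synthetases, Sars (1.49 ± 0.33, SE) and Eprs (0.94 ± 0.22) rose adjusted over the list alone and Aars (0.81 ± 0.25) did not pass. Their median was 0.25 (camera adjusted p = 0.00413, adjusted p = 0.570 with an estimated correlation). Translation factors were called up (median 0.34, with Eif2b4 at 0.81 ± 0.26, camera adjusted p = 0.00195, adjusted p = 0.570 with an estimated correlation). Acute phase genes were called up (0.42, with Apcs at 1.18 ± 0.38, camera adjusted p = 0.00609, adjusted p = 0.751 with an estimated correlation). So were immediate early genes (0.35, with Myc at 2.86 ± 0.98, camera adjusted p = 0.0122, adjusted p = 0.570 with an estimated correlation). Proteasome genes were called up as well (23 genes, 0.18, camera adjusted p = 0.0398, adjusted p = 0.876 with an estimated correlation). Genes of fatty acid synthesis were called down (13 genes, -0.65, with Thrsp at -1.60 ± 0.44, camera adjusted p = 0.00832, adjusted p = 0.751 with an estimated correlation). These 5 lists held 0 genes adjusted over the list alone by limma, and 5, 2, 2, 1 and 2 at an unadjusted p under 0.05 in the order given. By fry the stress regulators and synthetases had adjusted p = 0.121 and 0.182.

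Single genes of other lists also passed adjusted over the list alone in Atf4-/- livers, and none of them passed limma over all probe sets. Cdkn1a (1.33 ± 0.35, SE) and Gadd45a (2.32 ± 0.60) of 11 arrest genes, Igfbp1 of 10 genes of glucose metabolism and Rrm2 of 22 cell cycle genes rose adjusted over the list alone. The insulin receptor substrate gene Irs2 (-1.54 ± 0.37) of the glucose list and the tight junction gene Cldn7 (-1.0 ± 0.25) of 8 cholangiocyte markers fell adjusted over the list alone. Camera called none of these 4 lists. The transporter gene Slc38a2 stood at 1.2 ± 0.30, Xbp1 of the chaperone list at 0.98 ± 0.24 and the antioxidant gene Srxn1 at 1.43 ± 0.32, none past the test. Leaving out any 1 array kept Igfbp1's list at 1 gene or more and Rrm2's at 1. The count of 2 in the glucose list was 1 without either untreated Atf4-/- array, either treated Atf4+/+ array or treated Atf4-/- replicate 1. The arrest count of 2 was 1 without either untreated Atf4+/+ array and 0 without any other 1 array. The count of 1 cholangiocyte marker was 0 without any 1 array but untreated Atf4-/- replicate 2.

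Leaving out single arrays ended several calls in Atf4-/-. The count of stress regulators fell to 3 without treated replicate 2 and to 2 without treated replicate 1. Without treated replicate 1 camera also did not call acute phase (0.33, adjusted p = 0.114), immediate early (0.35, adjusted p = 0.0819), fatty acid synthesis (-0.44, adjusted p = 0.0978) or proteasome genes (0.12, adjusted p = 0.541). Without the array labelled untreated Atf4-/- replicate 2 it did not call acute phase (0.20, adjusted p = 0.450), fatty acid synthesis (-0.27, adjusted p = 0.418), proteasome (0.18, adjusted p = 0.254) or synthetase genes (0.14, adjusted p = 0.0846). Immediate early genes were not called without the array labelled untreated Atf4-/- replicate 1 (0.44, camera adjusted p = 0.122), where the acute phase median was 0.77 and the synthetase median 0.38. Their median was 0.56 without treated replicate 2. The count of 2 synthetases was 1 without untreated Atf4-/- replicate 2 and 0 without any other 1 array.

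The interaction asked whether the AP20187 effect differed by genotype, as the effect in Atf4-/- minus that in Atf4+/+, each measured against the untreated arrays with that label. In amino acid synthesis 3 of 10 genes had a smaller effect in Atf4-/- adjusted over the list alone: Psat1 (-3.34 ± 0.71, SE, 4 groups of 2 arrays), Mthfd2 (-2.38 ± 0.42, its other probe set at 1.35) and Psph (-1.37 ± 0.29). Of the 14 stress regulators Nupr1 had a smaller effect adjusted over the list alone (-6.43 ± 1.22), while Trib3 (-2.25 ± 0.95), Atf3 (-2.05 ± 0.65) and Ddit3 (-1.28 ± 0.68) did not pass. Of 20 synthetases 0 passed adjusted over the list alone by limma, and Lars (-1.25 ± 0.39), Gars (-0.96 ± 0.31) and Cars (-2.55 ± 1.05) had an unadjusted p under 0.05. Asns stood at -0.92 ± 0.47, and its other probe set at -3.64. The smallest p-values with higher values belonged to Mrvi1 (4.03 ± 0.29, limma adjusted p = 0.0666), Nid2 (4.82 ± 0.49), Crk (2.88 ± 0.32), Kif11 (2.48 ± 0.32) and the RNA-binding protein gene Ilf2 (3.29 ± 0.45). Those with lower values belonged to Dpt (-4.22 ± 0.34), the prostaglandin receptor gene Ptger3 (-3.85 ± 0.50, another probe set at 0.40), Ccr1 (-2.41 ± 0.34), Ccr3 (-2.90 ± 0.51) and Mthfd2. Atf4 stood at -3.43 ± 1.39 and Eif2ak3 at -0.19 ± 0.56. No probe set of 12422 passed limma over all probe sets. There were 678 with an unadjusted p under 0.05 (339 higher, 339 lower), where 621.1 would have it by chance.

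Camera called 8 of 37 lists in the interaction, and none held with an estimated correlation. Stress regulators had lower effects in Atf4-/- (median -0.59, camera adjusted p = 0.00483, adjusted p = 0.504 with an estimated correlation). So did synthetases (-0.29, camera adjusted p = 0.00621, adjusted p = 0.615 with an estimated correlation) and amino acid synthesis (-0.50, camera adjusted p = 0.0269, adjusted p = 0.504 with an estimated correlation). MHC class II genes were lower (-1.15, with H2-DMb1 at -1.91 ± 0.58, SE, camera adjusted p = 0.000696, adjusted p = 0.504 with an estimated correlation). Arrest genes were lower (-0.40, with Cdkn1a at -1.44 ± 0.50, camera adjusted p = 0.0376, adjusted p = 0.615 with an estimated correlation). Cholesterol synthesis was higher (0.94, with Msmo1 at 1.67 ± 0.65 and Mvd at 1.46 ± 0.63, camera adjusted p = 0.00107, adjusted p = 0.744 with an estimated correlation). The proteasome was higher (0.34, camera adjusted p = 0.0197, adjusted p = 0.744 with an estimated correlation). The urea cycle and amino acid breakdown were higher (0.36, with Tdo2 at 1.5 ± 0.63, camera adjusted p = 0.0376, adjusted p = 0.744 with an estimated correlation). The last 5 lists held 0 genes adjusted over the list alone by limma and 1, 1, 1, 1 and 0 at an unadjusted p under 0.05. By fry the stress, synthetase and amino acid synthesis lists had adjusted p = 0.223, 0.344 and 0.171. In lists not called, Rrm2 (2.11 ± 0.31) and the pancreas marker Clps (1.82 ± 0.38) were higher, and the lymphocyte marker Ccl5 (-2.57 ± 0.47) and the erythroid marker Gata1 (-2.88 ± 0.57, its other probe set at 0.25) lower, each adjusted over the list alone. Without treated Atf4-/- replicate 2 all 4 of these lists had a count of 0, and without treated Atf4+/+ replicate 2 all but that of Rrm2. The erythroid count was also 0 without untreated Atf4+/+ replicate 2, treated Atf4+/+ replicate 1 or treated Atf4-/- replicate 1. The pancreas count was also 0 without either untreated Atf4+/+ array or treated Atf4-/- replicate 1, and 2 without untreated Atf4-/- replicate 2 or treated Atf4+/+ replicate 1. The lymphocyte count was also 0 without untreated Atf4-/- replicate 2, and 2 without replicate 1 of untreated Atf4+/+, untreated Atf4-/- or treated Atf4+/+.

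Every array moved some call of the interaction. Without treated Atf4+/+ replicate 2 camera did not call synthetases (-0.22, adjusted p = 0.112), amino acid synthesis (-0.45, adjusted p = 0.112) or cholesterol (0.55, adjusted p = 0.0945). Nor did it then call arrest (-0.23, adjusted p = 0.179), proteasome (0.25, adjusted p = 0.239) or urea cycle genes (0.16, adjusted p = 0.461). Without the array labelled untreated Atf4+/+ replicate 2 it did not call cholesterol (0.53, adjusted p = 0.191), arrest (-0.41, adjusted p = 0.191), proteasome (0.33, adjusted p = 0.134) or urea cycle genes (0.40, adjusted p = 0.0984). Stress regulators (-0.63, camera adjusted p = 0.0503) and urea cycle genes (0.30, camera adjusted p = 0.0923) were not called without the array labelled untreated Atf4+/+ replicate 1, where the cholesterol median was 1.49. Amino acid synthesis was not called without treated Atf4+/+ replicate 1 (-0.58, camera adjusted p = 0.142), where the medians were 1.47 for cholesterol, -0.51 for synthetases and 0.60 for urea cycle genes. Without treated Atf4-/- replicate 1 camera did not call amino acid synthesis (-0.37, adjusted p = 0.0689), arrest (-0.37, adjusted p = 0.225), proteasome (0.32, adjusted p = 0.251) or urea cycle genes (0.28, adjusted p = 0.166). The median of amino acid synthesis was -0.28 without treated Atf4-/- replicate 2. Synthetases (-0.33, camera adjusted p = 0.0628), arrest (-0.34, camera adjusted p = 0.0628) and urea cycle genes (0.31, camera adjusted p = 0.138) were not called without the array labelled untreated Atf4-/- replicate 1, where the MHC class II median was -0.74. Amino acid synthesis (-0.40), arrest (-0.33), proteasome (0.29) and urea cycle genes (0.39) each had a camera adjusted p of 0.0735 without the array labelled untreated Atf4-/- replicate 2. The Nupr1 call over its list was lost without either untreated Atf4+/+ array, without untreated Atf4-/- replicate 2 and without treated Atf4+/+ replicate 2. That count was 2 without treated Atf4+/+ replicate 1, while the count of amino acid synthesis genes was 3 or 4 without any 1 array and 2 without both untreated arrays whose Atf4 level stood against their labels.

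**Figure D4:**
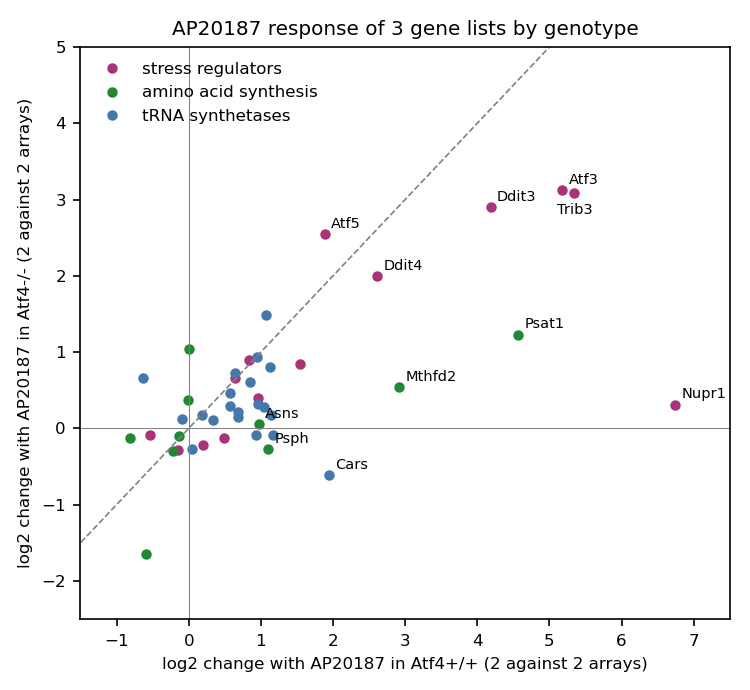
Log2 change with AP20187 of each gene of the stress regulator, amino acid synthesis and transfer RNA synthetase lists in Atf4-/- livers (vertical axis) against Atf4+/+ livers (horizontal axis), 2 against 2 arrays each. The dashed line marks equal changes. Nupr1 lay at 6.74 in Atf4+/+ and 0.31 in Atf4-/-, Psat1 at 4.57 and 1.23, and Atf3 at 5.18 and 3.13.

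The genotypes were then compared under AP20187, where the Atf4 level matched every label. In amino acid synthesis 3 of 10 genes were lower in treated Atf4-/- livers adjusted over the list alone. Psat1 had a ratio of 21.1 ± 3.36 in Atf4+/+ and 1.0 ± 0.438 in Atf4-/- (SD, n = 2 each), a log2 difference of -4.32 ± 0.50 (SE). Mthfd2 differed by -2.49 ± 0.30 (its other probe set by 0.91) and Psph by -1.13 ± 0.20, and Asns stood at -0.71 ± 0.33 (its other probe set at -1.93). Of 14 stress regulators 3 were lower adjusted over the list alone, Nupr1 (-4.50 ± 0.86), Atf3 (-2.28 ± 0.46, its other probe sets at -2.24 and 0.11) and the translation inhibitor gene Eif4ebp1 (-0.84 ± 0.21), while Trib3 (-1.92 ± 0.67) and Ddit3 (-1.02 ± 0.48) did not pass. Of 20 synthetases 18 had values below 0 and 5 were lower adjusted over the list alone, among them Gars (-1.16 ± 0.22), Nars (-1.29 ± 0.24), Lars (-1.10 ± 0.27) and Cars (-2.99 ± 0.74). The smallest p-values with lower values belonged to Psat1, Mthfd2, Dpt (-1.93 ± 0.24), Wdr55 (-1.74 ± 0.27) and Epb41l4a (-1.77 ± 0.28, its other probe set at 0.27). Those with higher values belonged to Crk (2.48 ± 0.23), Mrvi1 (2.17 ± 0.21), Kif11 (2.11 ± 0.23), Omt2b (1.30 ± 0.19) and the securin gene Pttg1 (1.67 ± 0.28). No probe set of 12422 passed limma over all probe sets (smallest adjusted p = 0.177). There were 659 with an unadjusted p under 0.05 (314 higher, 345 lower), where 621.1 would have it by chance.

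Camera called synthetases lower in treated Atf4-/- livers (median -0.43, camera adjusted p = 6.61e-08, adjusted p = 0.207 with an estimated correlation). It called stress regulators lower (-0.44, camera adjusted p = 0.000153, adjusted p = 0.207 with an estimated correlation) and amino acid synthesis lower (-0.46, camera adjusted p = 0.000632, adjusted p = 0.207 with an estimated correlation). The fry adjusted p of these 3 lists was 0.0608, 0.0608 and 0.0358. Interferon-induced genes were called lower (20 genes, -0.32, with Cxcl9 at -1.29 ± 0.44 and Gbp3 at -0.72 ± 0.27, SE, camera adjusted p = 0.00354, adjusted p = 0.333 with an estimated correlation). Translation factors were called lower (-0.22, camera adjusted p = 0.0418, adjusted p = 0.645 with an estimated correlation). The urea cycle and amino acid breakdown were called higher (0.28, with Gldc at 0.94 ± 0.43, camera adjusted p = 0.00591, adjusted p = 0.635 with an estimated correlation). Hepatocyte markers were called higher (20 genes, 0.19, camera adjusted p = 0.0296, adjusted p = 0.645 with an estimated correlation), as were chaperones of the endoplasmic reticulum (20 genes, 0.27, camera adjusted p = 0.0367, adjusted p = 0.658 with an estimated correlation). These 5 lists held 0 genes adjusted over the list alone by limma and 3, 1, 0, 0 and 1 at an unadjusted p under 0.05 in the order given. Clps was higher (1.33 ± 0.27) and Gata1 lower (-1.97 ± 0.40, its other probe set at 0.16) adjusted over their lists alone, which camera did not call. The Gata1 call ended without any 1 treated array, and the Clps call without any 1 treated array but Atf4+/+ replicate 1.

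Leaving out single treated arrays moved part of this. Without treated Atf4+/+ replicate 2 the count was 0 for stress regulators and 0 for synthetases, and the median of amino acid synthesis was -0.27. Camera then did not call urea cycle (0.16, adjusted p = 0.451), hepatocyte (0.09, adjusted p = 0.451), chaperone (0.29, adjusted p = 0.140) or translation genes (-0.12, adjusted p = 0.437). The synthetase count was 3 without treated Atf4+/+ replicate 1 and 2 without either array labelled untreated Atf4-/-. Without both untreated arrays whose Atf4 level stood against their labels, which enter here only through the spread, the counts were 0 stress regulators and 1 synthetase. Without treated Atf4-/- replicate 1 the counts were 1 and 0. Urea cycle (0.23, camera adjusted p = 0.0740), hepatocyte (0.21, camera adjusted p = 0.0740), chaperone (0.28, camera adjusted p = 0.238) and translation genes (-0.20, camera adjusted p = 0.113) were not called there. Without treated Atf4-/- replicate 2 the synthetase count was 0, hepatocyte (0.17, camera adjusted p = 0.106) and translation genes (-0.15, camera adjusted p = 0.112) were not called and the interferon median was -0.10. Chaperones were not called without treated Atf4+/+ replicate 1 (0.31, camera adjusted p = 0.188), where the medians were -0.80 for stress regulators and 0.33 for hepatocyte markers. Translation factors were not called without the array labelled untreated Atf4-/- replicate 1 or 2 (-0.22, camera adjusted p = 0.0562).

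Between the arrays labelled untreated Atf4-/- and untreated Atf4+/+ the smallest p-values with higher values in the arrays labelled Atf4-/- belonged to Ccr1 (2.45 ± 0.24, SE, 2 against 2 arrays), Dpt (2.29 ± 0.24), the calcium-binding protein gene S100g (1.94 ± 0.23, its other probe set at -0.55), Agr2 (2.16 ± 0.29, others at -0.24 and 0.64) and Bmp8b (1.86 ± 0.27). Those with lower values belonged to Rrm2 (-1.98 ± 0.22), Mrvi1 (-1.86 ± 0.21), the mitochondrial protease gene Yme1l1 (-2.33 ± 0.26), Ilf2 (-2.81 ± 0.32) and Bst1 (-2.07 ± 0.25). Adjusted over the list alone, Rrm2 of 22 cell cycle genes and Aldh18a1 (-1.71 ± 0.37, its other probe set at 0.11) of amino acid synthesis were lower in the arrays labelled Atf4-/-. The Aldh18a1 call ended without any 1 untreated array but the array labelled Atf4-/- replicate 2, and the cell cycle count was 2 without the array labelled untreated Atf4-/- replicate 1. MHC class II genes were called higher in these arrays (median 0.81, with H2-Eb1 at 1.49 ± 0.51 and H2-DMb1 at 1.38 ± 0.41, camera adjusted p = 0.000252, adjusted p = 0.927 with an estimated correlation). Cholesterol synthesis was called lower (-0.68, with Msmo1 at -1.09 ± 0.46 and Hmgcs1 at -0.90 ± 0.45, camera adjusted p = 0.00104, adjusted p = 0.927 with an estimated correlation). These lists held 0 genes adjusted over the list alone by limma and 2 and 0 at an unadjusted p under 0.05. No probe set of 12422 passed limma over all probe sets (smallest adjusted p = 0.134). There were 661 with an unadjusted p under 0.05 (343 higher, 318 lower), where 621.1 would have it by chance. MHC class II (0.41, camera adjusted p = 0.101) and cholesterol (-0.49, camera adjusted p = 0.101) were not called without the array labelled untreated Atf4-/- replicate 1, nor was cholesterol without the array labelled untreated Atf4+/+ replicate 2 (-0.07, camera adjusted p = 0.815). The MHC class II median was 1.24 without the array labelled untreated Atf4-/- replicate 2 and 0.39 without the array labelled untreated Atf4+/+ replicate 1, where the cholesterol median was -1.25.

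A held-out comparison removed the bias of choosing genes on the arrays that measure them. Chosen were the 100 probe sets with the largest rise between 1 untreated and 1 treated Atf4+/+ array. Their median log2 change was 0.57 in the other pair of Atf4+/+ arrays (range 0.16 to 0.91 over the 4 ways to choose) and 0.42 in the Atf4-/- arrays (range 0.15 to 0.68). The difference was not tested. The 100 with the largest fall had medians of -0.07 and -0.02. Across 8251 genes, which are not independent replicates, the AP20187 effects of the genotypes had Pearson's r = 0.227 and Spearman's rho = 0.220, with the same sign in 58.8%. Of 244 probe sets of genes within 20 Mb of Atf4, 0 passed limma between genotypes. At an unadjusted p under 0.05 there were 8 without AP20187 (3.28% against 5.19% of the other placed probe sets, Fisher's exact test, two-sided, p = 0.239) and 12 with it (4.92% against 5.15%, exact p = 1).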

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

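Of the tests below, both tests of the Atf4 level against the labels were set before their results were seen, and the tests of the smaller response in Atf4-/- and of cholesterol synthesis were chosen only after the result was seen.

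In 8 of the 37 gene lists the AP20187 effect differed between Atf4-/- and Atf4+/+ livers, as the untreated arrays are labelled, by camera with its preset correlation, each tested as an interaction over 4 groups of 2 arrays. The median difference, Atf4-/- minus Atf4+/+, was -1.15 for MHC class II (adjusted p = 0.000696, adjusted p = 0.504 with an estimated correlation) and 0.94 for cholesterol synthesis (adjusted p = 0.00107, adjusted p = 0.744 with an estimated correlation). It was -0.59 for stress regulators (adjusted p = 0.00483, adjusted p = 0.504 with an estimated correlation) and -0.29 for transfer RNA synthetases (adjusted p = 0.00621, adjusted p = 0.615 with an estimated correlation). The proteasome stood at 0.34 (adjusted p = 0.0197, adjusted p = 0.744 with an estimated correlation) and amino acid synthesis at -0.50 (adjusted p = 0.0269, adjusted p = 0.504 with an estimated correlation). The urea cycle and amino acid breakdown stood at 0.36 (adjusted p = 0.0376, adjusted p = 0.744 with an estimated correlation) and arrest genes at -0.40 (adjusted p = 0.0376, adjusted p = 0.615 with an estimated correlation). MHC class II and cholesterol synthesis also differed between the untreated arrays as labelled, with medians of 0.81 and -0.68, Atf4-/- minus Atf4+/+. Camera called neither list between the treated genotypes, so that both interactions lean on untreated arrays with doubted labels.

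The Atf4 level of 2 untreated arrays stood against their genotype labels. Differences at least as large within both untreated groups were found in 13 of 12422 probe sets (0.105%), below the bound set before. A rate over all probe sets does not tell how noisy this 1 probe set is, since its brightness is unknown. Noise of a single probe set was therefore not excluded. Exchanged labels of these arrays stayed open: among 693 probe sets that separated the treated genotypes, the split by Atf4 had a net count larger by 23 than the split by label, inside the band of 30.3 set before, with 68 in the same and 54 in the opposite direction by Atf4 and 49 and 58 by label. The remaining split of the untreated arrays, which neither names, had 63 in the same and 46 in the opposite direction, a net of 17 against 14 for the split by Atf4, so that the 23 was not particular to Atf4. By the same rule the untreated arrays were separated by 751 probe sets when split by label, 820 when split by Atf4 and 691 in the remaining split. The 693 of the treated genotypes are of the same size, so that their number does not set them apart from other splits. A single wrong label was not tested, and no biological explanation was tested.

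The stress, amino acid synthesis and synthetase lists were called with smaller AP20187 effects in Atf4-/- livers, but not with an estimated correlation (adjusted p = 0.504, 0.504 and 0.615 with an estimated correlation) or by fry (adjusted p = 0.223, 0.171 and 0.344). Wrong labels of untreated arrays were argued against as the whole cause. The 44 genes of these lists differed by a mean of -0.73 between the treated arrays alone, with 38 of 44 below 0. The SE of this mean was 0.17 over genes, which are not independent replicates. Between arrays it was 0.084, from the spread within all 4 groups, the untreated ones included. A smaller response of all genes stayed open. The held-out share was 0.735, the mean of the medians in Atf4-/- (0.42) over that in held-out Atf4+/+ arrays (0.57). It reads the 100 probe sets with the largest rise and not all genes. Against this share the lists lay lower by a mean of -0.34 (SE 0.15). The share of a single choice ranged from 0.321 to 2.64 over the 4 ways to choose, and against the lowest the lists lay at 0.15 (SE 0.11). A need for ATF4 at these genes, the biological explanation the design names, may account for the difference and remains a hypothesis. The bounds for excluding both technical explanations were made stricter after their results were seen.

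Cholesterol synthesis was called lower with AP20187 in Atf4+/+ livers by camera with its preset correlation (adjusted p = 0.421 with an estimated correlation). An untreated array with a high level could be the source. Without untreated Atf4+/+ replicate 2 the median was -0.65. The SE between arrays, computed for the difference of list means and not for this median, was 0.354, a spread that left this source open. Time of day or feeding, read by the clock gene Dbp alone, stayed open as well. The other clock genes did not enter this test. The list mean had Spearman's rho = -0.24 with Dbp over the 8 arrays (exact permutation p = 0.582) and Pearson's r = 0.15 (exact permutation p = 0.741), and without the 2 arrays farthest from the median of Dbp r was -0.68 and rho -0.77. The bound of the first of these tests was made stricter after its result was seen, and an effect of AP20187 itself also stayed open.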

How the results depend on the processing

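Alternatives chosen after seeing the data were pseudocounts of 0 and 0.4, leaving out row medians below 0.99, the probe set with the highest mean, the 4 untreated arrays as 1 group, leaving out both arrays with doubted labels, and leaving out both arrays at the ends of the cholesterol list. The others were planned. Planned pseudocounts of 1 and 64 and the planned percentile filters were not run, because the table held ratios. Array weights leave the means of groups of 2 unchanged. No paired analysis was possible because the labels give no pairing of arrays across groups. An array left alone in its group was assumed to vary like the others.

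In Atf4+/+ livers the medians of stress regulators, synthetases, translation factors, acute phase and arrest genes kept their direction and stayed past camera in 20 of 20 alternatives that used the preset correlation. So did those of stress regulators and translation factors in Atf4-/- livers. With an estimated correlation the number of lists called was 0 in each of the 5 comparisons. The test then allows for genes of a list that vary together, but it also rests on 4 residual degrees of freedom. Which of these ended the calls was not tested.

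The count of probe sets past the test in Atf4+/+ livers, 1 as reported, was 2 with quantile normalization, 8 with low row medians left out, where fewer were tested, and 15 at an adjusted p under 0.10. It was 0 with only the 2 groups compared and 0 without both doubted arrays, where fewer arrays estimate the spread. It was 17 with the conflicting array moved to untreated Atf4+/+ and 22 with the 4 untreated arrays as 1 group, where more arrays stand in the reference. With trend and robust fitting it was 1, a probe set of Atf3 and not B3galt1. In Atf4-/- livers 1 passed at an adjusted p under 0.10. In the interaction, 0 as reported by limma with 678 at an unadjusted p under 0.05, 2 passed with low row medians left out, 2 with probe sets of a gene averaged and 2 at an adjusted p under 0.10. Leaving out 1 array gave 0 to 0 in Atf4+/+ livers.

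Of gene lists called in the interaction, 8 as reported, 5 were called with quantile normalization and 5 with averaged probe sets. With the conflicting array moved 12 were called in Atf4-/- livers and 4 between the untreated genotypes. Without both doubted arrays 4 were called in Atf4-/- livers and 4 between the untreated genotypes. Of the 37 list calls reported, 13 ended without both doubted arrays with the sign of the median kept, and a further 1, amino acid synthesis in Atf4+/+ livers, ended with it changed. The 13 were in Atf4+/+ livers urea cycle and immediate early, in Atf4-/- livers synthetases, fatty acid synthesis, acute phase and proteasome, in the interaction amino acid synthesis, cholesterol, urea cycle, arrest and proteasome, between the untreated genotypes cholesterol, and between the treated genotypes translation factors. With the conflicting array moved 1 list, amino acid synthesis in Atf4+/+ livers, changed sign and stayed called, and 8 calls ended: MHC class II in Atf4+/+ livers, immediate early in Atf4-/- livers, cholesterol, urea cycle, arrest and MHC class II in the interaction, and both lists between the untreated genotypes. Leaving out 1 array gave 7 to 12 lists in Atf4+/+ livers, 3 to 12 in Atf4-/- livers, 2 to 8 in the interaction, 1 to 6 between the untreated and 5 to 12 between the treated genotypes. In the held-out comparison 50 probe sets gave medians of 1.19 in Atf4+/+ and 0.79 in Atf4-/- livers, and 200 gave 0.32 and 0.22, against 0.57 and 0.42 as reported. For these list and held-out counts the cause was not tested.

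The median of amino acid synthesis in Atf4+/+ livers, -0.01 as reported, changed sign to 0.027 with median centring, 0.031 with the highest-mean probe set, 0.00148 with low row medians left out, 0.42 with the conflicting array moved, 0.48 with the 4 untreated arrays as 1 group and 0.15 without both doubted arrays. Without 1 array it lay between -0.13 and 0.30. The arrays at the ends of the cholesterol list were chosen on its own values, so that its median without them, -0.26, decides nothing.

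Single genes changed sign as well. With the highest-mean probe set, which is another probe set of the gene, Igfbp1 in Atf4+/+ was -0.57, Agr2 and Aldh18a1 between the untreated genotypes were -0.24 and 0.11, and Epb41l4a between the treated genotypes was 0.27. Asns in Atf4-/- was -0.88 with averaged probe sets. With low row medians left out another probe set stood for Ccr1, at 0.68 in Atf4-/- and 0.030 in the interaction. Phgdh in Atf4+/+ was 0.018 with median centring, and Eif2ak3 between the untreated genotypes was 0.00232 with a pseudocount of 0.4. With the conflicting array moved, Slc7a11 was 0.43 and Phgdh 0.16 in Atf4+/+, Nupr1 was -0.48 and Asns -0.069 in Atf4-/-, Eif2ak3 was 0.55 in the interaction and Atf4 1.28 between the untreated genotypes. With the 4 untreated arrays as 1 group Slc7a11 was 0.36 and Phgdh 0.10. Without both doubted arrays Phgdh was 0.14 in Atf4+/+, and Eif2ak3 was -0.50 in Atf4-/- and 0.71 between the untreated genotypes. Where no construction shows it, the cause was not tested.

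Leaving out 1 array gave ranges that crossed 0 for genes that had not passed the test. In Atf4+/+ livers these were -1.36 to 0.73 for Slc7a11 and -0.28 to 0.25 for Phgdh. In Atf4-/- livers they were -0.85 to 1.47 for Nupr1, -0.27 to 0.38 for Asns and -0.50 to 0.62 for Eif2ak3. Eif2ak3 ranged from -0.75 to 0.37 in the interaction, from -0.58 to 0.54 between the untreated and from -0.43 to 0.00647 between the treated genotypes. Atf4 ranged from -1.57 to 1.05 between the untreated genotypes.

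In a table of ratios the signal over background is unknown, so that a change of a dim probe set and noise near its floor were not separated by brightness.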

Other observations

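No test of the values below was chosen only after the result was seen.

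Camera called 20 of the 37 lists in none of the 5 comparisons (smallest adjusted p = 0.0952, for cholangiocytes in Atf4-/- livers). Their medians in Atf4+/+ and Atf4-/- livers were -0.15 and -0.13 for 12 amino acid transporters, -0.13 and -0.13 for 18 antioxidant genes, -0.20 and -0.09 for 19 genes of fatty acid oxidation, -0.39 and -0.18 for 10 genes of glucose metabolism and -0.22 and -0.13 for 18 cytochromes P450. They were -0.05 and 0.00 for 22 cell cycle genes and 0.08 and -0.17 for 15 clock genes. Markers of other cells stood at 0.12 and -0.07 for Kupffer cells, -0.03 and -0.22 for lymphocytes, -0.31 and -0.09 for neutrophils, -0.17 and -0.29 for erythroid cells and -0.24 and -0.15 for endothelium. They stood at -0.18 and -0.05 for stellate cells, -0.25 and -0.66 for cholangiocytes, 0.03 and 0.18 for pancreas, -0.09 and -0.18 for adipocytes and 0.04 and -0.13 for muscle. Genes higher in male liver stood at -0.48 and 0.06, those higher in female liver at -0.37 and -0.72, and 4 genes of the sex chromosomes at 0.12 and 0.53. These 4 join a gene high in females with genes of the Y chromosome, so that their joint median does not read the sex of the mice.

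In Atf4+/+ livers Igfbp1 of the glucose list (2.04 ± 0.25, SE, 2 against 2 arrays) rose adjusted over the list alone, also without any 1 array, but its other probe set stood at -0.57. Srxn1 of the antioxidant list (1.56 ± 0.32, its other probe set at -0.11) rose adjusted over the list alone, a call that ended without any 1 array but treated Atf4+/+ replicate 1. Gata1 of the erythroid list (2.05 ± 0.40, its other probe set at 0.01) rose, a call that ended without untreated Atf4+/+ replicate 2 or either treated Atf4+/+ array. Ccl5 of the lymphocyte list (1.63 ± 0.33) rose, a call that ended without any 1 array but replicate 1 of untreated or treated Atf4+/+, the count being 3 without the latter. Myh4 of the muscle list (-1.52 ± 0.26, another probe set at 0.38) fell, a call that ended without either untreated Atf4+/+ array or treated Atf4+/+ replicate 1, the count being 2 without treated Atf4+/+ replicate 2.

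Treated Atf4+/+ replicate 2 had 552 probe sets with a ratio of at least 2, and replicate 1 had 235. For the clock genes chosen after values had been seen, the ratios in untreated Atf4+/+ replicate 2 were 5.37 for Dbp, 5.21 for Nr1d1, 0.20 for Arntl and 0.25 for Cry1. In treated Atf4-/- replicate 1 Nr1d1 was 4.09 and Cry1 0.29, and in treated Atf4+/+ replicate 2 Dbp was 3.87.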
